A study of Mus musculus with 22 samples.

How the data were processed

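The deposited tables held counts, CPM and RPKM for 41388 genes in each of 22 libraries. Per the submitters' processing notes, reads were handled with bcl2fastq, STAR 2.0.4b, Subread and featureCounts 1.45 on GRCm38, without a statement of the annotation release, the strand setting or any filter. Per the labels' protocols, macrophages were sorted as live CD45+ CD11b+ F4/80+ cells with high or low MHC class II, negative for CD3, CD19, B220, SiglecF, Ly6G and Ly6C. Per the labels, libraries were made with the Clontech SMARTer kit (version 1), and PDAC tissue was digested for 25 min and the other tissues for 15 min. The deposited CPM columns were the counts scaled to the same total in each library, to within 5.1e-11. The deposited RPKM columns were those CPM values per kb of the length column, to within 5.1e-11. Symbols were found for 40254 of the gene identifiers and not for 1134, 16 identifiers shared a symbol, and 30665 had the start and end of GENCODE M21. Levels in the text are CPM computed from the counts, on library totals adjusted by the TMM factors described next.

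The counts of all 22 libraries were fitted together in edgeR 4.0.16 (R 4.3.3), with 1 coefficient for each of the 6 groups of tissue state and YFP fraction. Genes were kept by filterByExpr at a minimum count of 10 and a minimum total of 15, which left 15801. Libraries were scaled by TMM factors, and each comparison was tested with the quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. There were 12 comparisons. YFP-negative was compared with YFP-positive in each of 3 tissues, the tissues were compared within each fraction, and 3 interactions tested whether a change between tissues differed between the fractions. Log2 fold changes are edgeR's, and their SE is the log2 fold change divided by the square root of the F value. The tests, the lists, the comparisons and the rule for named genes were chosen before the data were examined.

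Gene lists were tested in each comparison with camera in limma 3.58.1, at a preset correlation between genes of 0.01, with adjustment over 29 lists per comparison. Of these, 18 were macrophage programmes and 11 were markers of other cell types. The lists held 789 symbols, of which 776 were in the files, 3 of them under a synonym, and 721 were tested. Camera with an estimated correlation and limma's fry were run beside it. Some markers of other cell types are also expressed by macrophages, and lists share members, so that a list's change does not by itself identify a cell.

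The genes named in the text come from sets made by rule, and not every member of a set is named. In each of the 9 comparisons of groups these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between libraries, without members of lists for other cell types, unnamed or predicted genes, pseudogenes, receptor segments of lymphocytes, Y-linked genes and Xist. Added were up to 4 called members of each programme list with the smallest adjusted p, the most abundant member where fewer than 2 were called, the most abundant member of each list of other cell types, and Adgre1, Csf1r, Lyve1, Cx3cr1, Ccr2, H2-Ab1 and Flt3 throughout. For the interactions the rule took the 6 largest positive and the 6 largest negative differences with at least 20 CPM in the highest group, and the list members by the same rule. Genes that share reads with near copies, such as C4b, Ear2, H2-DMb2, H2-DMb1 and Mgl2, are uncertain, as are genes that overlap another gene on either strand.

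Replicate numbers are shared by the groups in the labels, which do not say whether they mark the same animals. In PDAC the deviations of YFP-negative and YFP-positive libraries from their group means correlated at 0.221 to 0.392 within a number and at most at -0.00407 between numbers. YFP-positive libraries of PDAC and pancreatitis correlated at 0.111 to 0.185 within a number and at most at 0.0882 between numbers. Both pairings come from the data alone.

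The methods were tried on simulated counts drawn from the real means and library sizes, with 200 changed genes among 15801. For the comparisons of groups, edgeR found 36 to 56% of changes of 2-fold and 79 to 94% of changes of 4-fold, with 4 to 11 false calls. For the interactions it found 7 to 12% and 56 to 71%, with 3 false calls in each. The sign was wrong for 0 of the changed genes called. DESeq2 1.42.0 had 9.44 to 22.8% false calls among its calls. Camera found the changed list in 12 of 12 simulated comparisons and called 0 random lists. The simulated genes were drawn independently of each other, so this cannot show how often camera calls lists of correlated genes falsely.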

Results

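Macrophages were sorted from the pancreas of Flt3-Cre;LSL-YFP mice and their RNA was sequenced in 22 libraries. In these mice Cre recombinase expressed from the Flt3 gene switches on YFP for good, so that YFP marks cells that descend from Flt3-expressing progenitors. Each of 3 tissue states gave a YFP-positive and a YFP-negative fraction. The steady-state pancreas and the pancreas in pancreatitis gave 4 libraries per fraction. Pancreatitis followed injections of cerulein, a cholecystokinin analogue that injures acinar cells, at 100 µg/kg and 6 injections per treatment day. Pancreatic ductal adenocarcinoma (PDAC), grown from 100000 implanted KPC cells of mouse pancreatic cancer, gave 3 libraries per fraction. Total counts per library ran from 15348875 to 21561885 (YFP-positive) and from 16080249 to 20063413 (YFP-negative) at steady state. In pancreatitis they ran from 15699815 to 25422510 and from 20162170 to 27925878, and in PDAC from 35909019 to 40994684 and from 30427143 to 36589160. Levels are mean CPM on library totals adjusted by TMM factors ± SD over the libraries of a group, n = 4 outside PDAC and n = 3 in PDAC. Positions are on GRCm38. Adjusted p-values are from edgeR's quasi-likelihood test for genes and from limma's camera for gene lists, the latter also given with an estimated correlation between genes where that ended the call. List members are counted as called at an adjusted p under 0.05 over all genes, and again, in parentheses, with the adjustment made over the list alone. For every gene described as higher or lower, all libraries of one group lay above all those of the other unless stated.

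The tissues parted first. The first principal component held 40.2% of the variance, and the PDAC libraries lay between 88.9 and 127 on it, all others between -80.5 and -16.8. Transcripts of acinar cells, the enzyme-secreting cells of the pancreas, varied with the tissue in both fractions. Genes of the acinar list held 7.21 ± 1.97% of the counts in YFP-negative and 5.84 ± 3.37% in YFP-positive macrophages at steady state. They held 0.707 ± 0.170% and 0.805 ± 0.407% in pancreatitis and 0.446 ± 0.215% and 0.109 ± 0.0848% in PDAC. Mitochondrially encoded genes held 7.13 ± 0.729% of the counts in PDAC YFP-negative and 2.82 ± 0.462% in PDAC YFP-positive libraries, and 0.911 to 1.59% on average in the other groups. Steady-state YFP-negative replicate 4 and pancreatitis YFP-positive replicate 2 stood apart from their groups, with mean correlations to the other replicates of 0.922 and 0.928, against 0.948 to 0.983 for the other libraries.

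**Figure D1:**
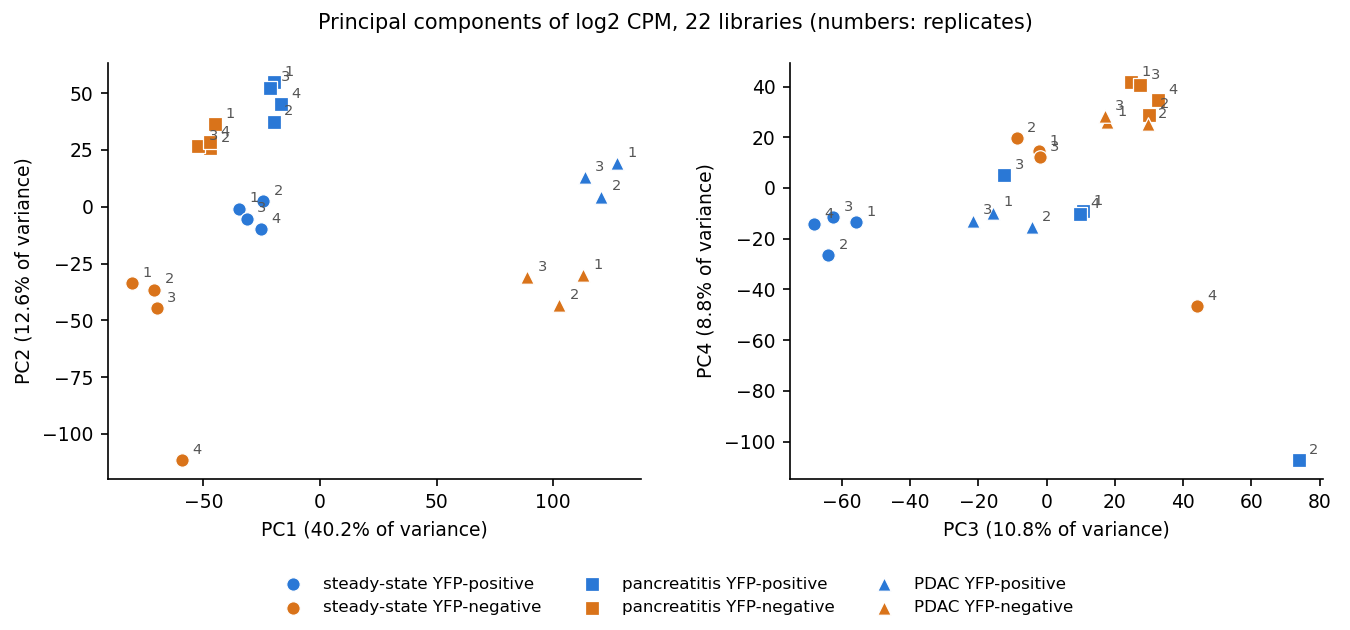
Each point is 1 of 22 libraries, placed by its scores on the first 4 principal components of log2 CPM, with colour for the YFP fraction, shape for the tissue state and a number for the replicate. PDAC libraries lie between 88.9 and 127 on the first component, steady-state YFP-negative replicate 4 lies lowest on the second and pancreatitis YFP-positive replicate 2 lowest on the fourth.

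**Figure D2:**
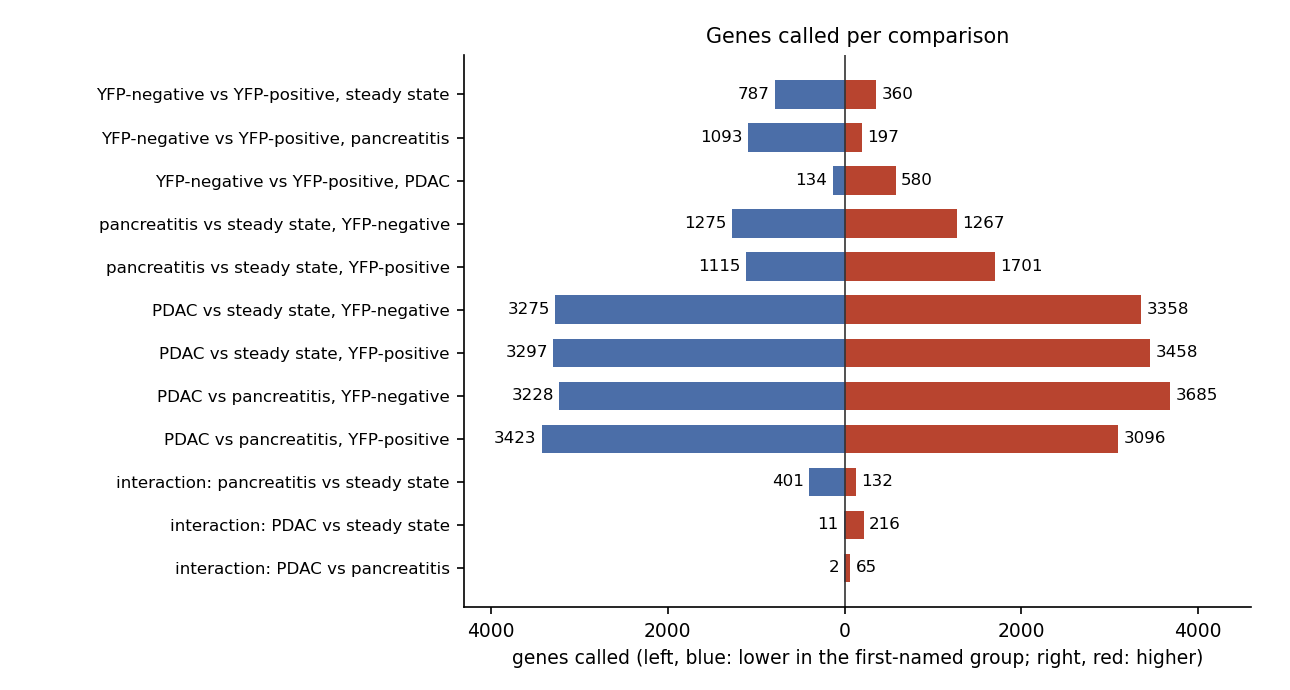
Bars give the number of genes called by edgeR at an adjusted p under 0.05 in each comparison, higher in the first-named group to the right and lower to the left. The counts run from 67 genes for the interaction of PDAC and pancreatitis to 6913 for PDAC against pancreatitis in YFP-negative macrophages.

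How do YFP-negative macrophages differ from YFP-positive ones? At steady state the YFP-negative fraction had lower levels of genes of monocyte-derived cells. Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), the chemokine receptor that lets monocytes leave the bone marrow, was at 92.1 ± 20.6 against 645 ± 146 CPM, 7.01-fold lower (log2 fold change -2.81, SE 0.29, adjusted p = 1.74e-06). Napsa (ENSMUSG00000002204, chromosome 7, 44572432 to 44586862), which encodes the aspartic protease napsin A, was at 3.88 ± 1.37 against 54.7 ± 5.58 CPM, 14.1-fold lower (log2 fold change -3.82, SE 0.27, adjusted p = 1.49e-08). Fgr, a Src-family kinase of myeloid cells, was 8.97-fold lower, Gpr35 10.1-fold lower and Lsp1 4.42-fold lower. The list of monocyte and monocyte-derived genes was lower (camera adjusted p = 1.72e-23). Among the 30 monocyte genes, 18 were lower and 12 not called (21 lower over the list alone). Genes of antigen presentation on MHC class II were lower (camera adjusted p = 4.45e-11), and H2-DMb2, a subunit of the peptide-loading chaperone, was 5.68-fold lower. In the MHC class II list, 10 were lower and 7 not called of 17 (12 lower over the list alone). Lower too were the lists of lipid-associated and lysosomal genes (camera adjusted p = 6e-07) and of immune checkpoint and suppression genes (camera adjusted p = 2.01e-05). Of 36 genes in the lipid-associated and lysosomal list, 1 was higher, 9 lower and 26 not called (2 higher and 16 lower over the list alone). Among the 24 immune checkpoint and suppression genes, 1 was higher, 7 lower and 16 not called (1 higher and 12 lower over the list alone). Gpnmb, a glycoprotein of lipid-laden macrophages, was 6.15-fold lower, and Havcr2, which encodes the checkpoint receptor TIM-3, 3.89-fold lower.

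Some genes of the extracellular matrix (ECM) were higher in YFP-negative macrophages at steady state. Col3a1, a fibrillar collagen chain, was at 19.3 ± 13.9 against 2.60 ± 0.477 CPM (log2 fold change 2.89, SE 0.39, adjusted p = 4.8e-05). Sparc, a collagen-binding matrix protein, was 2.58-fold higher and Dcn, the proteoglycan decorin, 2.19-fold higher. The collagen list (camera adjusted p = 1.03e-05, adjusted p = 0.106 with an estimated correlation) and the list of ECM glycoproteins and proteoglycans (camera adjusted p = 0.000265, adjusted p = 0.106 with an estimated correlation) rose on balance. In the collagen list, 5 were higher and 14 not called of 19 (11 higher over the list alone). Of 34 genes in the ECM glycoprotein and proteoglycan list, 6 were higher, 2 lower and 26 not called (13 higher and 2 lower over the list alone). The fibroblast and stellate cell list, which shares Col3a1 and Dcn, moved with them (camera adjusted p = 0.000609, adjusted p = 0.054 with an estimated correlation). Among the 29 fibroblast genes, 6 were higher, 2 lower and 21 not called (10 higher and 2 lower over the list alone). Mitochondrially encoded genes, at 1.59 ± 0.44% of counts against 0.995 ± 0.119%, were higher as a list too (camera adjusted p = 0.00343, adjusted p = 0.171 with an estimated correlation). In the mitochondrially encoded list, 2 were higher and 6 not called of 8 (4 higher over the list alone). Colec12, a scavenger receptor, was 2.21-fold higher, within a tissue-resident macrophage list that was higher (camera adjusted p = 0.000452, adjusted p = 0.171 with an estimated correlation). Of 29 genes in the tissue-resident list, 3 were higher and 26 not called (6 higher over the list alone). Markers of lymphocytes fell with the monocyte genes. The T and NK cell list summed to 65.6 ± 5.46 CPM against 230.3 ± 65.5 (camera adjusted p = 4.86e-32). Among the 27 T and NK cell genes, 21 were lower and 6 not called (24 lower over the list alone). Csf1r, the receptor for macrophage colony-stimulating factor, was at 3295 ± 820.5 against 3256 ± 269.8 CPM, Adgre1, which encodes F4/80, at 2053 ± 1189 against 2112 ± 158 CPM and Lyve1 at 1635 ± 341 against 1467 ± 180.0 CPM (adjusted p = 0.977, 0.96 and 0.77). In all, 1147 of 15801 genes were called, 360 higher and 787 lower. Of all genes tested, 2423 had no overlap between the libraries of the groups (2.86% by chance). The count was 533 when only these groups were fitted and 1870 with DESeq2. It was 747 and 763 without YFP-positive replicates 3 and 2, and 1981 without YFP-negative replicate 2.

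The same question was put to the inflamed pancreas. In pancreatitis, YFP-negative macrophages had higher levels of genes of tissue-resident macrophages (camera adjusted p = 1.05e-12). In the tissue-resident list, 8 were higher and 21 not called of 29 (14 higher and 1 lower over the list alone). Vsig4 (ENSMUSG00000044206, chromosome X, 96247203 to 96293438), a complement receptor of resident macrophages, was at 485 ± 57.2 against 182 ± 18.3 CPM, 2.67-fold higher (log2 fold change 1.42, SE 0.16, adjusted p = 5.07e-05). The chemokine gene Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799) was at 5058 ± 645 against 2184 ± 326 CPM, 2.32-fold higher (log2 fold change 1.21, SE 0.18, adjusted p = 0.000784). The complement list was higher on balance (camera adjusted p = 8.74e-05, adjusted p = 0.0903 with an estimated correlation), with C2, the protease of the classical pathway, 3.29-fold higher. Of 22 genes in the complement list, 5 were higher, 3 lower and 14 not called (7 higher and 4 lower over the list alone). Ccn1, a matricellular protein, was 3.16-fold higher and the proteoglycan Lum (lumican) 2.44-fold higher. Camera did not call the collagen list (adjusted p = 0.818).

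Napsa was 3.85-fold lower in YFP-negative macrophages in pancreatitis and H2-DMb2 4.03-fold lower, and the lists of monocyte-derived genes (camera adjusted p = 6.94e-06, adjusted p = 0.0903 with an estimated correlation) and MHC class II genes (camera adjusted p = 3.92e-05, adjusted p = 0.0903 with an estimated correlation) were lower. Among the 30 monocyte genes, 7 were lower and 23 not called (11 lower over the list alone). In the MHC class II list, 7 were lower and 10 not called of 17 (1 higher and 8 lower over the list alone). Ccr2 was at 504 ± 163 against 524 ± 205 CPM (adjusted p = 0.933). Cell cycle genes were lower as a list (camera adjusted p = 4.53e-09, adjusted p = 0.266 with an estimated correlation), among them Spc24, a kinetochore subunit, at 2.65 ± 0.903 against 10.2 ± 4.31 CPM. Of 49 genes in the cell cycle list, 12 were lower and 37 not called (17 lower over the list alone). T and NK cell genes were lower as well (camera adjusted p = 3.87e-19). Among the 27 T and NK cell genes, 18 were lower and 9 not called (21 lower over the list alone). In all, 1290 genes were called, 197 higher and 1093 lower, and 2148 genes tested had no overlap (2.86% by chance). The count was 164 when only these groups were fitted and 1968 with DESeq2. It was 683 without YFP-positive replicate 2, which stood apart from its group, 2119 without YFP-positive replicate 3, and 533, 654, 541 and 666 without YFP-negative replicates 1, 2, 3 and 4.

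Which genes differ between the fractions in the tumour? In PDAC, genes of the extracellular matrix were higher in YFP-negative macrophages. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) was at 165 ± 53.8 against 7.55 ± 2.25 CPM in YFP-negative and YFP-positive macrophages, 21.8-fold higher (log2 fold change 4.45, SE 0.46, adjusted p = 3.83e-06). Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55420080) was at 375 ± 98.3 against 26.4 ± 4.76 CPM, 14.2-fold higher (log2 fold change 3.83, SE 0.25, adjusted p = 6.34e-09). Bgn (biglycan) was 12.9-fold higher, Dcn 17.1-fold higher, Col1a2 19.5-fold higher and Lum 19.9-fold higher. The collagen list (camera adjusted p = 2.71e-25) and the ECM glycoprotein and proteoglycan list (camera adjusted p = 2.23e-27) rose. In the collagen list, 12 were higher and 7 not called of 19 (14 higher over the list alone). Of 34 genes in the ECM glycoprotein and proteoglycan list, 16 were higher and 18 not called (22 higher and 1 lower over the list alone). The fibroblast and stellate cell list rose with them (camera adjusted p = 7.52e-42), from a sum of 718 ± 35.1 CPM in YFP-positive to 1179.7 ± 219 in YFP-negative libraries. Among the 29 fibroblast genes, 20 were higher and 9 not called (21 higher and 1 lower over the list alone). Other transcripts moved the same way. Mitochondrially encoded genes were higher (camera adjusted p = 3.33e-09), and the acinar list was higher (camera adjusted p = 1.13e-20, adjusted p = 0.111 with an estimated correlation), at a sum of 4049.8 ± 1953 CPM against 1087 ± 833. In the mitochondrially encoded list, 6 were higher and 2 not called of 8 (8 higher over the list alone). Of 50 genes in the acinar cell list, 9 were higher and 41 not called (41 higher over the list alone). Cela2a, an acinar elastase, was at 850.1 ± 502 against 202 ± 177 CPM (adjusted p = 0.061, and 0.00127 with the replicate number as a block).

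YFP-negative macrophages of PDAC also had higher levels of genes of tissue-resident macrophages (camera adjusted p = 1.03e-19). Among the 29 tissue-resident genes, 16 were higher and 13 not called (21 higher over the list alone). Vsig4 was 2.85-fold higher, Timd4, a phosphatidylserine receptor for apoptotic cells, 2.97-fold higher and Colec12 4.23-fold higher. Complement genes were higher by the test (camera adjusted p = 0.00108, adjusted p = 0.111 with an estimated correlation), with a median log2 fold change of -0.07 and a mean of 0.51, among them C2, 6.20-fold higher, and Serping1, the C1 inhibitor, 15.9-fold higher. In the complement list, 6 were higher and 16 not called of 22 (8 higher over the list alone). Lower were Prpf19, a splicing factor and ubiquitin ligase, at 6.27 ± 0.880 against 34.2 ± 6.05 CPM, and Arpc3, a subunit of the actin-nucleating Arp2/3 complex, at 218 ± 25.2 against 775 ± 37.0 CPM. The MHC class II list was lower (camera adjusted p = 1.07e-05, adjusted p = 0.0583 with an estimated correlation), and so was the T and NK cell list (camera adjusted p = 6.75e-10). Of 17 genes in the MHC class II list, 3 were lower and 14 not called (10 lower over the list alone). Among the 27 T and NK cell genes, 3 were lower and 24 not called (12 lower over the list alone). Ccr2 was at 419.6 ± 71.0 against 658 ± 96.0 CPM (adjusted p = 0.271). In all, 714 genes were called, 580 higher and 134 lower, and 7139 genes tested had no overlap (10% by chance with 3 libraries against 3). The count was 150 with the acinar share as a covariate, 4121 (53.4% higher) when only these groups were fitted, 1294 with DESeq2 and 5302 (47.2% higher) with limma voom. It was 306 and 438 without YFP-positive replicates 1 and 2, and 326 and 429 without YFP-negative replicates 2 and 3.

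**Figure D3:**
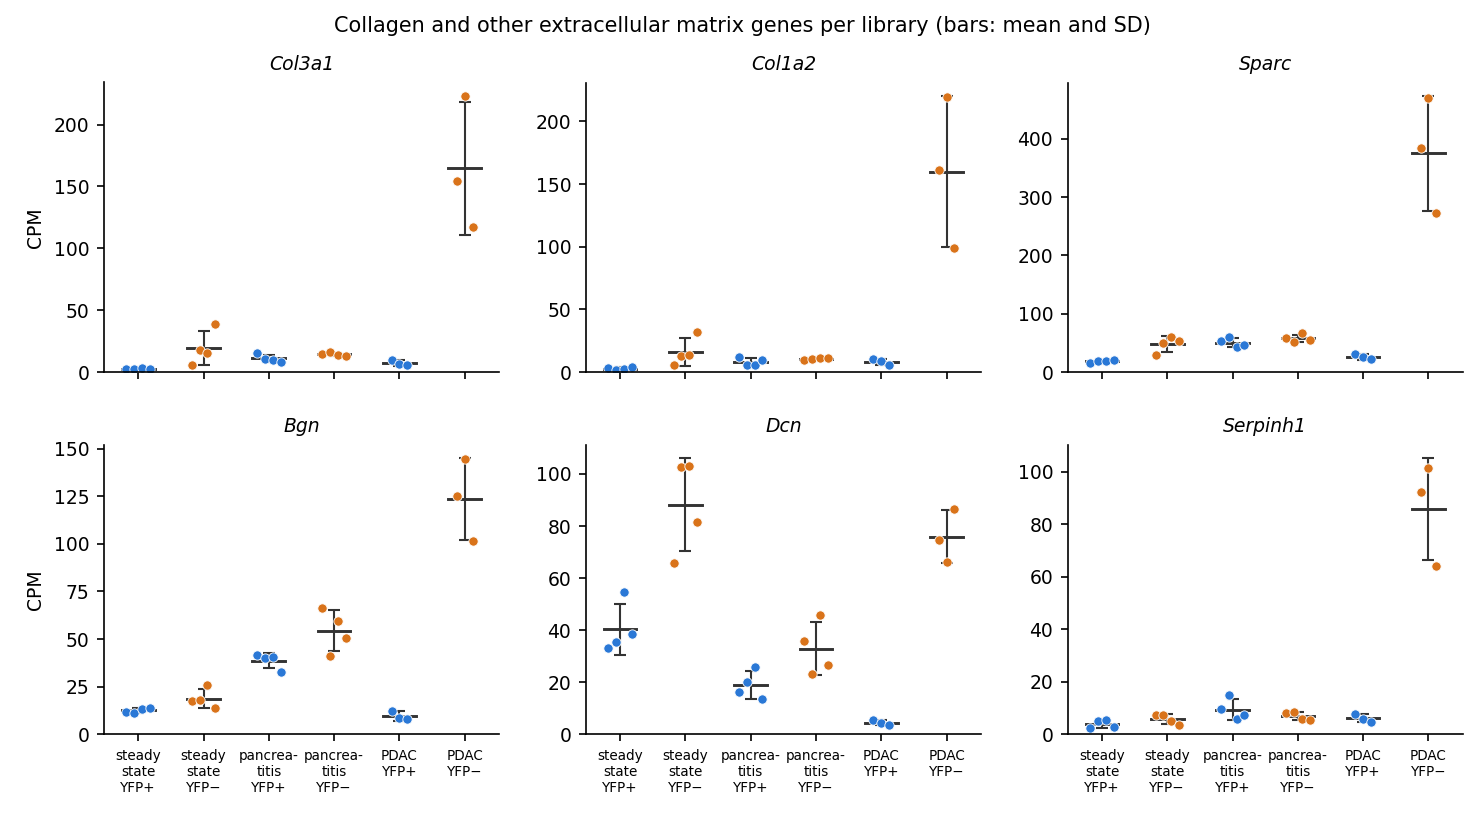
CPM of Col3a1, Col1a2, Sparc, Bgn, Dcn and Serpinh1 in each library (points) with the mean and SD of each group (bars), YFP-positive in blue and YFP-negative in orange. In PDAC, Sparc averaged 375 CPM in YFP-negative and 26.4 CPM in YFP-positive macrophages.

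Genes called between the fractions overlapped across tissues, in comparisons that share no library. Steady state and pancreatitis shared 41 genes higher and 249 lower in YFP-negative macrophages, against 4.49 and 54.4 for independent lists. Steady state and PDAC shared 110 higher and 67 lower, against 13.2 and 6.67. Pancreatitis and PDAC shared 87 higher and 78 lower, against 7.23 and 9.27. C2, Ccn1 and Colec12 were higher in YFP-negative macrophages in all 3 tissues. Col3a1 and Sparc were higher at steady state and in PDAC.

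**Figure D4:**
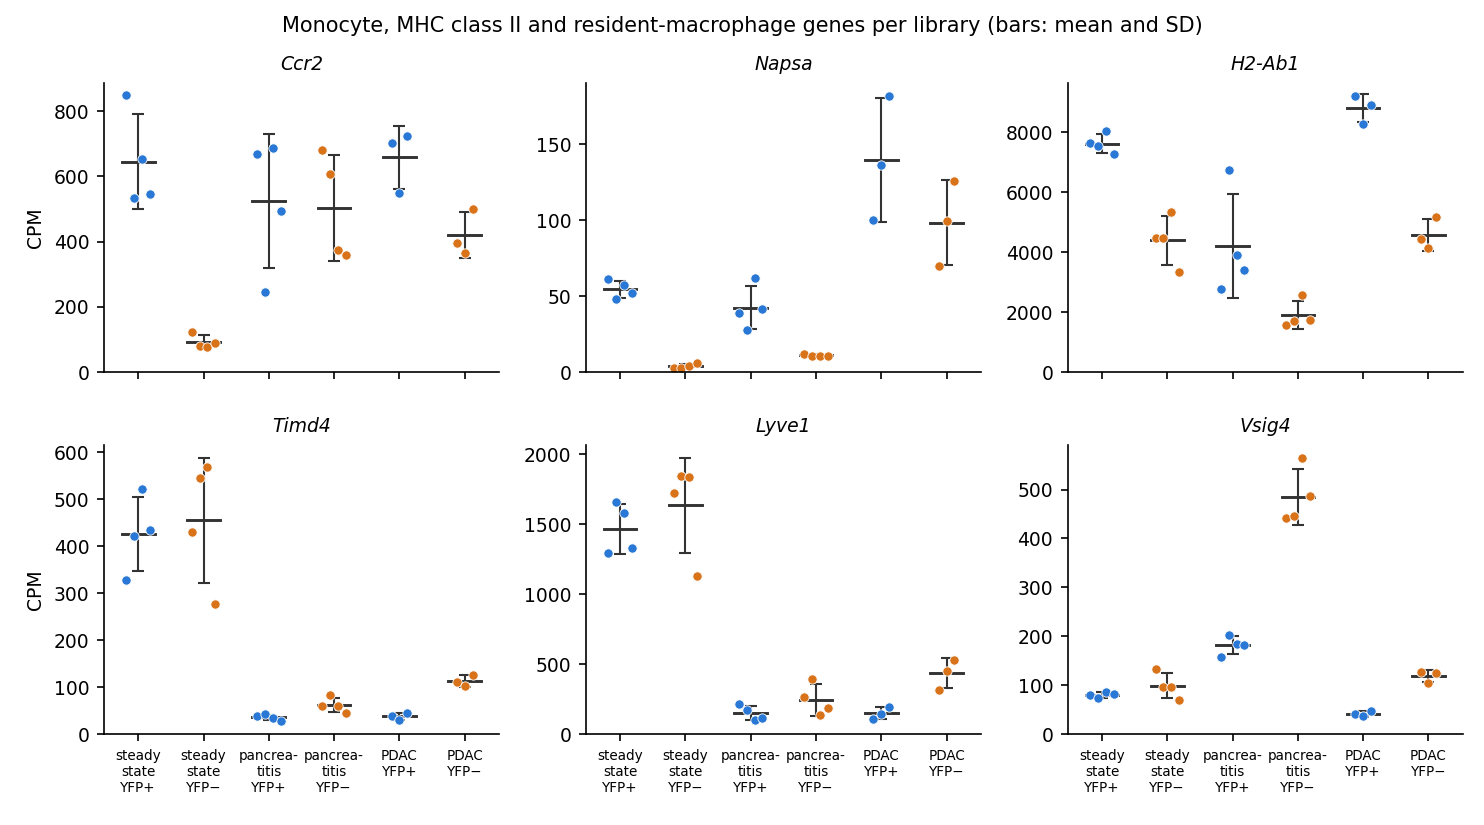
CPM of Ccr2, Napsa, H2-Ab1, Timd4, Lyve1 and Vsig4 in each library (points) with the mean and SD of each group (bars), YFP-positive in blue and YFP-negative in orange. Ccr2 averaged 92.1 CPM in steady-state YFP-negative macrophages and between 419.6 and 658 CPM in the other 5 groups.

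What does pancreatitis change in each fraction? In YFP-negative macrophages, lipid-associated and lysosomal genes rose (camera adjusted p = 1.73e-27). In the lipid-associated and lysosomal list, 28 were higher, 2 lower and 6 not called of 36 (29 higher and 2 lower over the list alone). Ctsd (ENSMUSG00000007891, chromosome 7, 142371148 to 142388038), the lysosomal protease cathepsin D, rose from 2158 ± 759 to 11807 ± 939.6 CPM, 5.47-fold (log2 fold change 2.45, SE 0.21, adjusted p = 9.67e-08). Trem2, a lipid-sensing receptor, rose 3.74-fold and Gpnmb 10.0-fold. Spp1, which encodes osteopontin, rose 12.4-fold, Ccl8 7.10-fold and Vsig4 4.90-fold. Ccr2 rose from 92.1 ± 20.6 to 504 ± 163 CPM, 5.48-fold (log2 fold change 2.45, SE 0.29, adjusted p = 4.56e-06). Immune checkpoint and suppression genes (camera adjusted p = 0.000134) and complement genes (camera adjusted p = 0.000496, adjusted p = 0.116 with an estimated correlation) rose as lists, the latter with C6, a component of the membrane attack complex, 6.88-fold. Of 24 genes in the immune checkpoint and suppression list, 8 were higher, 1 lower and 15 not called (10 higher and 2 lower over the list alone). Among the 22 complement genes, 8 were higher and 14 not called (9 higher over the list alone). Neutrophil genes rose from a sum of 98.7 ± 18.7 to 200.9 ± 20.8 CPM (camera adjusted p = 0.000282), and cell cycle genes were higher (camera adjusted p = 1.57e-05, adjusted p = 0.415 with an estimated correlation). In the neutrophil list, 6 were higher and 9 not called of 15 (7 higher over the list alone). Of 49 genes in the cell cycle list, 19 were higher, 1 lower and 29 not called (20 higher and 1 lower over the list alone). Mgl2, a galactose-type lectin of alternatively activated macrophages, fell from 1452 ± 333 to 87.8 ± 14.1 CPM (log2 fold change -4.05, SE 0.27, adjusted p = 3.18e-09). Timd4 was 7.30-fold lower, Lyve1, a hyaluronan receptor of resident macrophages, 6.64-fold lower, and the matrix protease gene Mmp9 29.1-fold lower. Acinar genes fell as a list (camera adjusted p = 2.39e-27, adjusted p = 0.116 with an estimated correlation). Among the 50 acinar cell genes, 5 were higher, 36 lower and 9 not called (7 higher and 39 lower over the list alone). In all, 2542 genes were called, 1267 higher and 1275 lower, and 3441 genes tested had no overlap (2.86% by chance). The count was 212 with the acinar share as a covariate, 1530 when only these groups were fitted, and 1590 without pancreatitis YFP-negative replicate 1.

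In YFP-positive macrophages, pancreatitis raised lipid-associated and lysosomal genes as well (camera adjusted p = 2.62e-12). In the lipid-associated and lysosomal list, 19 were higher, 2 lower and 15 not called of 36 (23 higher and 2 lower over the list alone). Ctsd rose from 3399 ± 367 to 12183 ± 967 CPM, 3.58-fold (log2 fold change 1.84, SE 0.21, adjusted p = 3.83e-06). Trem2 rose 4.11-fold, Spp1 7.85-fold, the cholesterol exporter gene Abca1 3.04-fold and Sparc 2.72-fold. Cell cycle genes were higher as a list (camera adjusted p = 3.85e-06, adjusted p = 0.36 with an estimated correlation). Of 49 genes in the cell cycle list, 22 were higher, 1 lower and 26 not called (31 higher and 1 lower over the list alone). Mgl2 fell from 1771 ± 337 to 105 ± 21.0 CPM (log2 fold change -4.08, SE 0.27, adjusted p = 5.73e-09). Retnla, a secreted marker of alternative activation, was 16.4-fold lower, Ccl24 11.6-fold lower and the fatty acid transporter gene Cd36 4.71-fold lower, and the alternative activation list was lower (camera adjusted p = 1.36e-06, adjusted p = 0.0607 with an estimated correlation). Among the 24 alternative activation genes, 3 were higher, 10 lower and 11 not called (4 higher and 14 lower over the list alone). Timd4 was 11.9-fold lower and Lyve1 9.54-fold lower, and the tissue-resident list was lower (camera adjusted p = 8.75e-06, adjusted p = 0.139 with an estimated correlation). In the tissue-resident list, 4 were higher, 11 lower and 14 not called of 29 (7 higher and 15 lower over the list alone). MHC class II genes were lower as a list (camera adjusted p = 1.57e-05, adjusted p = 0.107 with an estimated correlation), with H2-Eb1 2.97-fold lower. Of 17 genes in the MHC class II list, 2 were higher, 8 lower and 7 not called (3 higher and 10 lower over the list alone). Ccr2 was at 524 ± 205 against 645 ± 146 CPM (adjusted p = 0.49). The acinar list was lower (camera adjusted p = 3.22e-19, adjusted p = 0.154 with an estimated correlation). Among the 50 acinar cell genes, 7 were higher, 30 lower and 13 not called (7 higher and 36 lower over the list alone). In all, 2816 genes were called, 1701 higher and 1115 lower, and 3107 genes tested had no overlap (2.86% by chance). The count was 604 with the acinar share as a covariate, 1351 when only these groups were fitted, and 1872 without steady-state YFP-positive replicate 4. The fractions shared 464 genes that were higher and 503 that were lower in pancreatitis, against 136 and 90.0 for independent lists.

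Did the fractions respond differently to pancreatitis? The test of the difference between the changes called 533 genes, 132 with a larger rise or smaller fall in YFP-negative macrophages, given as higher, and 401 with the opposite, given as lower. Ccr2 rose from 92.1 ± 20.6 to 504 ± 163 CPM in YFP-negative macrophages and was at 645 ± 146 and 524 ± 205 CPM in YFP-positive ones (log2 difference 2.75, SE 0.39, adjusted p = 0.00144). Fgr rose from 9.69 ± 2.16 to 64.5 ± 11.6 CPM, against 86.9 ± 11.4 and 109 ± 15.8 (log2 difference 2.41, SE 0.24, adjusted p = 2.67e-05). Gpr35 (log2 difference 2.89, SE 0.39, adjusted p = 0.000683), Fcrl1 (log2 difference 2.48, SE 0.39, adjusted p = 0.0058) and Napsa (log2 difference 1.87, SE 0.35, adjusted p = 0.0134) differed in the same direction. So did the monocyte list (camera adjusted p = 1.1e-06, adjusted p = 0.0978 with an estimated correlation) and the lipid-associated and lysosomal list (camera adjusted p = 0.000276, adjusted p = 0.199 with an estimated correlation). In the monocyte list, 6 were higher and 24 not called of 30 (7 higher and 1 lower over the list alone). Of 36 genes in the lipid-associated and lysosomal list, 1 was higher, 1 lower and 34 not called (3 higher and 1 lower over the list alone). The collagen list differed in the opposite direction (camera adjusted p = 0.000576, adjusted p = 0.328 with an estimated correlation). Among the 19 collagen genes, 2 were lower and 17 not called (5 lower over the list alone). The count was 188 (60.6% higher) with the replicate number as a block, 131 with the acinar share as a covariate, 16 when only these groups were fitted, 1283 with DESeq2, 328 with limma voom and 891 without a filter on low counts. It was 71, 201, 50 and 55 without steady-state YFP-positive replicates 1 to 4, 1078 and 145 without steady-state YFP-negative replicates 2 and 4, 348, 1555 and 881 without pancreatitis YFP-positive replicates 2, 3 and 4, and 44, 60, 127 and 176 without pancreatitis YFP-negative replicates 1 to 4.

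What distinguishes macrophages of the tumour? In PDAC, whose tissue was digested longer, YFP-negative macrophages had higher levels of inflammatory and hypoxia-related genes than at steady state. Il1rn (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494), which encodes the interleukin-1 receptor antagonist, rose from 9.86 ± 3.14 to 747 ± 119 CPM, 75.8-fold (log2 fold change 6.24, SE 0.29, adjusted p = 2.43e-12). Il1b rose from 33.8 ± 15.97 to 1924 ± 188 CPM, and Ptgs2, the inducible cyclooxygenase, from 4.004 ± 2.35 to 517 ± 128 CPM. The inflammatory cytokine and NF-kB list rose (camera adjusted p = 4.55e-13). In the inflammatory cytokine and NF-kB list, 23 were higher and 11 not called of 34 (23 higher over the list alone). The glucose transporter gene Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137330) rose from 6.49 ± 1.87 to 211 ± 40.7 CPM, 32.5-fold (log2 fold change 5.02, SE 0.28, adjusted p = 2.7e-11), and Hilpda, a hypoxia-induced lipid droplet protein, 43.5-fold, with the glycolysis and hypoxia list (camera adjusted p = 5.9e-25). Of 37 genes in the glycolysis and hypoxia list, 31 were higher and 6 not called (31 higher over the list alone). ECM remodelling genes rose (camera adjusted p = 1.06e-12), with the collagenase gene Mmp13 12.5-fold and Tgm2, a matrix cross-linking transglutaminase, 53.6-fold. Among the 38 ECM remodelling genes, 29 were higher, 3 lower and 6 not called (30 higher and 4 lower over the list alone). Checkpoint and suppression genes rose (camera adjusted p = 7.35e-08). In the immune checkpoint and suppression list, 14 were higher, 3 lower and 7 not called of 24 (14 higher and 3 lower over the list alone). Nt5e, the ectonucleotidase CD73, was at 89.9 ± 12.1 against 0.513 ± 0.299 CPM. Acp5, a lysosomal phosphatase of osteoclasts and macrophages, rose 37.8-fold, Spp1 64.9-fold and Mki67, a marker of dividing cells, 7.30-fold, with cell cycle genes higher as a list (camera adjusted p = 3.48e-11, adjusted p = 0.115 with an estimated correlation). Of 49 genes in the cell cycle list, 34 were higher and 15 not called (35 higher over the list alone).

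Matrix genes rose in YFP-negative macrophages of PDAC as well, with Col1a1 at 168 ± 72.4 against 6.13 ± 4.01 CPM, in the lists of collagens (camera adjusted p = 7.22e-07, adjusted p = 0.0777 with an estimated correlation) and of ECM glycoproteins and proteoglycans (camera adjusted p = 2.33e-08), beside the fibroblast and stellate cell list (camera adjusted p = 4.52e-06). Among the 19 collagen genes, 14 were higher and 5 not called (14 higher over the list alone). In the ECM glycoprotein and proteoglycan list, 19 were higher, 3 lower and 12 not called of 34 (19 higher and 3 lower over the list alone). Of 29 genes in the fibroblast list, 19 were higher, 4 lower and 6 not called (19 higher and 4 lower over the list alone). Monocyte genes rose (camera adjusted p = 6.14e-11), with Napsa 25.4-fold and Plac8 29.0-fold. Among the 30 monocyte genes, 22 were higher, 4 lower and 4 not called (22 higher and 4 lower over the list alone). Tissue-resident genes fell (camera adjusted p = 1.42e-07), with Folr2, a folate receptor, 4.70-fold lower, Timd4 4.02-fold lower and the scavenger receptor gene Stab1 3.55-fold lower. In the tissue-resident list, 2 were higher, 22 lower and 5 not called of 29 (3 higher and 22 lower over the list alone). Adgre1 was 3.63-fold lower (log2 fold change -1.86, SE 0.42, adjusted p = 0.00116), with overlapping libraries. Nr1d1, a repressor of the circadian clock, was at 4.44 ± 1.80 against 148 ± 60.3 CPM (log2 fold change -5.05, SE 0.36, adjusted p = 1.11e-09). Neutrophil genes rose (camera adjusted p = 6.14e-11), among them Il1r2, the decoy receptor for interleukin-1, at 347 ± 73.4 against 0.353 ± 0.264 CPM. Of 15 genes in the neutrophil list, 12 were higher, 1 lower and 2 not called (12 higher and 1 lower over the list alone). The acinar list was lower (camera adjusted p = 5.64e-22, adjusted p = 0.0931 with an estimated correlation) and mitochondrially encoded genes were higher (camera adjusted p = 9.12e-06, adjusted p = 0.062 with an estimated correlation). Among the 50 acinar cell genes, 46 were lower and 4 not called (46 lower over the list alone). In the mitochondrially encoded list, 8 were higher of 8 (8 higher over the list alone). In all, 6633 genes were called, 3358 higher and 3275 lower, and 6937 genes tested had no overlap (5.71% by chance). The count was 1377 with the acinar share as a covariate.

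Inflammatory genes rose in YFP-positive PDAC macrophages too (camera adjusted p = 1.34e-08, adjusted p = 0.104 with an estimated correlation). Of 34 genes in the inflammatory cytokine and NF-kB list, 20 were higher and 14 not called (23 higher over the list alone). Il1rn rose from 38.7 ± 13.4 to 1031 ± 127 CPM, 26.7-fold (log2 fold change 4.74, SE 0.27, adjusted p = 6.9e-11), and Ptgs2 from 10.5 ± 5.20 to 486 ± 136 CPM. The cytokine gene Osm rose 22.7-fold and Spp1 31.5-fold. Glycolysis and hypoxia genes rose (camera adjusted p = 7.27e-23), with Slc2a1 17.6-fold (log2 fold change 4.14, SE 0.27, adjusted p = 4.82e-10) and Hilpda 30.7-fold. Among the 37 glycolysis and hypoxia genes, 30 were higher, 1 lower and 6 not called (30 higher and 1 lower over the list alone). ECM remodelling genes rose (camera adjusted p = 7.45e-09), with Mmp13 21.3-fold, and so did checkpoint and suppression genes (camera adjusted p = 5.96e-05), with Nt5e at 105 ± 15.9 against 2.14 ± 0.387 CPM. In the ECM remodelling list, 23 were higher, 4 lower and 11 not called of 38 (23 higher and 5 lower over the list alone). Of 24 genes in the immune checkpoint and suppression list, 13 were higher, 5 lower and 6 not called (13 higher and 5 lower over the list alone). Cell cycle genes were higher as a list (camera adjusted p = 6.74e-12, adjusted p = 0.177 with an estimated correlation). Among the 49 cell cycle genes, 40 were higher and 9 not called (40 higher over the list alone). Of the collagen list, 8 genes were higher, 3 lower and 8 not called, and camera did not call the list (adjusted p = 0.0733). Dcn was 9.08-fold lower. Tissue-resident genes fell (camera adjusted p = 1.54e-14), with Folr2 9.63-fold lower and Timd4 11.2-fold lower. In the tissue-resident list, 2 were higher, 23 lower and 4 not called of 29 (3 higher and 23 lower over the list alone). Nr1d1 was at 3.75 ± 0.329 against 163 ± 56.5 CPM. Ccr2 was at 658 ± 96.0 against 645 ± 146 CPM and H2-Ab1, an MHC class II chain, at 8794 ± 469 against 7614 ± 318 CPM (adjusted p = 0.949 and 0.512). Neutrophil genes rose (camera adjusted p = 1.58e-07) and the acinar list fell (camera adjusted p = 1.09e-31, adjusted p = 0.0759 with an estimated correlation). Of 15 genes in the neutrophil list, 10 were higher, 1 lower and 4 not called (11 higher and 1 lower over the list alone). Among the 50 acinar cell genes, 50 were lower (50 lower over the list alone). In all, 6755 genes were called, 3458 higher and 3297 lower, and 9318 genes tested had no overlap (5.71% by chance). The count was 358 with the acinar share as a covariate. The fractions shared 2488 genes higher and 2415 lower in PDAC, against 735 and 683 for independent lists.

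**Figure D5:**
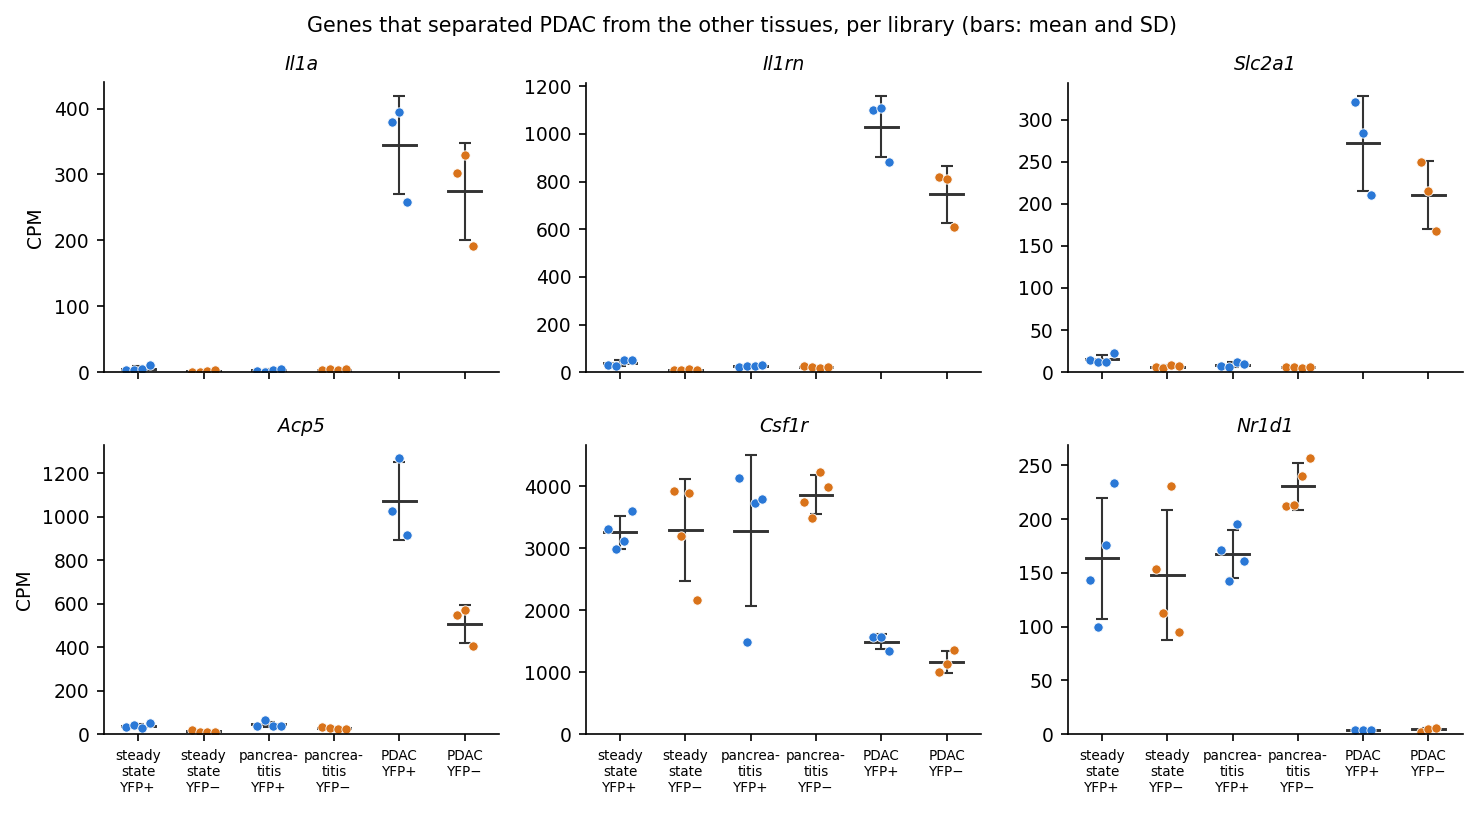
CPM of Il1a, Il1rn, Slc2a1, Acp5, Csf1r and Nr1d1 in each library (points) with the mean and SD of each group (bars), YFP-positive in blue and YFP-negative in orange. Il1rn averaged 747 CPM in YFP-negative and 1031 CPM in YFP-positive macrophages of PDAC, against 9.86 to 38.7 CPM in the other groups.

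The change from steady state to PDAC differed between the fractions in 227 genes, 216 of them with a larger rise or smaller fall in YFP-negative macrophages. Bgn rose from 18.7 ± 4.99 to 124 ± 21.6 CPM in YFP-negative macrophages and was at 12.5 ± 1.34 and 9.60 ± 2.41 CPM in YFP-positive ones (log2 difference 3.10, SE 0.30, adjusted p = 7.37e-06). Sparc (log2 difference 2.47, SE 0.31, adjusted p = 0.000123), Dcn (log2 difference 2.96, SE 0.37, adjusted p = 0.000123) and Lum (log2 difference 3.89, SE 0.49, adjusted p = 0.000123) differed in the same direction, as did the lists of ECM glycoproteins and proteoglycans (camera adjusted p = 4.26e-14), collagens (camera adjusted p = 4.98e-07, adjusted p = 0.0664 with an estimated correlation) and fibroblast and stellate cell genes (camera adjusted p = 3.68e-22). In the ECM glycoprotein and proteoglycan list, 6 were higher and 28 not called of 34 (12 higher over the list alone). Of 19 genes in the collagen list, 3 were higher and 16 not called (9 higher over the list alone). Among the 29 fibroblast genes, 9 were higher and 20 not called (19 higher over the list alone). Monocyte genes also rose more in YFP-negative macrophages (camera adjusted p = 2.33e-14), with Napsa (log2 difference 3.32, SE 0.38, adjusted p = 5.71e-05) and Ccr2 (log2 difference 2.16, SE 0.42, adjusted p = 0.0104). In the monocyte list, 7 were higher and 23 not called of 30 (11 higher over the list alone). T and NK cell genes differed that way too (camera adjusted p = 4.85e-11). Of 27 genes in the T and NK cell list, 3 were higher and 24 not called (10 higher over the list alone). Arpc3 was at 218 ± 25.2 and 426 ± 104 CPM in YFP-negative macrophages of PDAC and steady state, and at 775 ± 37.0 and 513 ± 54.4 CPM in YFP-positive ones (log2 difference -1.57, SE 0.28, adjusted p = 0.00638). The count was 90 with the acinar share as a covariate, 441 with DESeq2 and 862 (56.4% higher) with limma voom, and 102, 104 and 99 without PDAC YFP-positive replicates 1 and 2 and YFP-negative replicate 2. Without the 2 outlying libraries, an alternative chosen after seeing the data, it was 746.

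What separates the tumour from the inflamed pancreas? In YFP-negative macrophages of PDAC, the matrix protease genes Mmp13 and Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850) were at 233 ± 21.9 against 2.19 ± 0.806 CPM and 516 ± 106 against 13.6 ± 3.46 CPM, the latter 37.9-fold higher (log2 fold change 5.24, SE 0.30, adjusted p = 5.47e-11). ECM remodelling genes rose as a list (camera adjusted p = 3.09e-09). Among the 38 ECM remodelling genes, 27 were higher, 4 lower and 7 not called (28 higher and 4 lower over the list alone). Collagen genes rose (camera adjusted p = 4.72e-09), with Col1a2 14.9-fold, and so did fibroblast and stellate cell genes (camera adjusted p = 6.2e-08). In the collagen list, 18 were higher and 1 not called of 19 (19 higher over the list alone). Of 29 genes in the fibroblast list, 22 were higher and 7 not called (25 higher over the list alone). Il1rn rose from 22.4 ± 3.38 to 747 ± 119 CPM (log2 fold change 5.06, SE 0.27, adjusted p = 2.41e-11), with the inflammatory list (camera adjusted p = 1.12e-12). Among the 34 inflammatory cytokine and NF-kB genes, 26 were higher, 1 lower and 7 not called (26 higher and 1 lower over the list alone). Glycolysis and hypoxia genes rose (camera adjusted p = 8.79e-22), with Slc2a1 35.6-fold. In the glycolysis and hypoxia list, 31 were higher, 2 lower and 4 not called of 37 (31 higher and 3 lower over the list alone). The integrin gene Itgax, which encodes CD11c, was 25.9-fold higher and H2-DMb2 16.4-fold higher, and the MHC class II list was higher (camera adjusted p = 0.00119, adjusted p = 0.122 with an estimated correlation). Of 17 genes in the MHC class II list, 10 were higher, 1 lower and 6 not called (10 higher and 1 lower over the list alone). Complement genes (camera adjusted p = 0.00561, adjusted p = 0.148 with an estimated correlation) and tissue-resident genes (camera adjusted p = 8.5e-05, adjusted p = 0.105 with an estimated correlation) were lower, with Vsig4 4.06-fold lower, C4b 4.33-fold lower and Stab1 4.04-fold lower. Among the 22 complement genes, 3 were higher, 10 lower and 9 not called (3 higher and 10 lower over the list alone). In the tissue-resident list, 6 were higher, 18 lower and 5 not called of 29 (6 higher and 19 lower over the list alone). Lipid-associated and lysosomal genes were lower on balance (camera adjusted p = 0.0125, adjusted p = 0.235 with an estimated correlation), with Grn, the lysosomal protein progranulin, 4.08-fold lower and Cd68 3.49-fold lower. Of 36 genes in the lipid-associated and lysosomal list, 8 were higher, 20 lower and 8 not called (8 higher and 20 lower over the list alone). Csf1r was 3.32-fold lower and Adgre1 5.75-fold lower. Mitochondrially encoded genes were higher (camera adjusted p = 5.42e-10). Among the 8 mitochondrially encoded genes, 8 were higher (8 higher over the list alone). In all, 6913 genes were called, 3685 higher and 3228 lower, and 9841 genes tested had no overlap (5.71% by chance).

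In YFP-positive macrophages, Mmp9 rose from 21.3 ± 7.77 in pancreatitis to 742 ± 271 CPM in PDAC, 34.9-fold (log2 fold change 5.13, SE 0.30, adjusted p = 5.59e-11), and ECM remodelling genes rose as a list (camera adjusted p = 7.91e-08). In the ECM remodelling list, 21 were higher, 6 lower and 11 not called of 38 (21 higher and 6 lower over the list alone). Il1rn rose 39.7-fold (log2 fold change 5.31, SE 0.27, adjusted p = 1.49e-11) with the inflammatory list (camera adjusted p = 2.52e-13). Of 34 genes in the inflammatory cytokine and NF-kB list, 23 were higher, 1 lower and 10 not called (24 higher and 2 lower over the list alone). Slc2a1 rose 30.04-fold with the glycolysis and hypoxia list (camera adjusted p = 8.93e-27), and H2-DMb2 6.57-fold with the MHC class II list (camera adjusted p = 0.000233, adjusted p = 0.0941 with an estimated correlation). Among the 37 glycolysis and hypoxia genes, 31 were higher, 1 lower and 5 not called (31 higher and 2 lower over the list alone). In the MHC class II list, 11 were higher, 1 lower and 5 not called of 17 (12 higher and 1 lower over the list alone). Of the collagen list, 4 genes were higher, 3 lower and 12 not called (camera adjusted p = 0.688). Bgn was 4.02-fold lower and Dcn 4.25-fold lower. Complement genes (camera adjusted p = 0.00711, adjusted p = 0.194 with an estimated correlation) and tissue-resident genes (camera adjusted p = 1.12e-07, adjusted p = 0.0563 with an estimated correlation) were lower, with Vsig4 4.33-fold lower, C4b 6.02-fold lower and Folr2 6.67-fold lower. Of 22 genes in the complement list, 2 were higher, 10 lower and 10 not called (2 higher and 10 lower over the list alone). Among the 29 tissue-resident genes, 3 were higher, 19 lower and 7 not called (3 higher and 19 lower over the list alone). Ctrb1, an acinar chymotrypsinogen, was at 70.4 ± 58.2 against 1288 ± 771 CPM, and the acinar list fell (camera adjusted p = 3.9e-14, adjusted p = 0.194 with an estimated correlation). In the acinar cell list, 38 were lower and 12 not called of 50 (40 lower over the list alone). In all, 6519 genes were called, 3096 higher and 3423 lower, and 6934 genes tested had no overlap (5.71% by chance). The count was 2245 with the acinar share as a covariate. The fractions shared 2456 genes higher and 2221 lower, against 722 and 699 for independent lists.

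The change from pancreatitis to PDAC differed between the fractions in 67 genes, 65 of them with a larger rise or smaller fall in YFP-negative macrophages. Serpinh1, the collagen chaperone HSP47, rose from 6.94 ± 1.70 to 85.8 ± 19.4 CPM in YFP-negative macrophages and was at 9.42 ± 4.03 and 6.07 ± 1.52 CPM in YFP-positive ones (log2 difference 4.25, SE 0.48, adjusted p = 5.2e-05). Sparc (log2 difference 3.62, SE 0.31, adjusted p = 1.71e-06), Bgn (log2 difference 3.19, SE 0.30, adjusted p = 3.83e-06), Col3a1 (log2 difference 4.06, SE 0.56, adjusted p = 0.000736) and Mgp (log2 difference 3.41, SE 0.50, adjusted p = 0.00146) differed the same way, as did the lists of collagens (camera adjusted p = 2.13e-24), of ECM glycoproteins and proteoglycans (camera adjusted p = 2.48e-23) and of fibroblast and stellate cell genes (camera adjusted p = 4.38e-34). Of 19 genes in the collagen list, 6 were higher and 13 not called (14 higher over the list alone). Among the 34 ECM glycoprotein and proteoglycan genes, 7 were higher and 27 not called (19 higher over the list alone). In the fibroblast list, 12 were higher and 17 not called of 29 (19 higher over the list alone). Mitochondrially encoded genes (camera adjusted p = 5.79e-10) and acinar genes (camera adjusted p = 4.15e-24, adjusted p = 0.137 with an estimated correlation) moved with them. Of 8 genes in the mitochondrially encoded list, 8 were not called (8 higher over the list alone). Among the 50 acinar cell genes, 50 were not called (39 higher over the list alone). Arpc3 went the other way, at 218 ± 25.2 and 521 ± 99.6 CPM in YFP-negative and 775 ± 37.0 and 614 ± 121 CPM in YFP-positive macrophages (log2 difference -1.60, SE 0.28, adjusted p = 0.00935). The count was 112 with the replicate number as a block, 20 with the acinar share as a covariate, 280 with DESeq2, 636 with limma voom and 254 without the 2 outlying libraries. It was 41, 40, 42 and 42 without pancreatitis YFP-negative replicates 1 to 4, 31, 35 and 28 without PDAC YFP-positive replicates 1 to 3, and 25 without PDAC YFP-negative replicate 2.

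Pancreatitis and PDAC were both compared with the same steady-state libraries. In YFP-negative macrophages the comparisons shared 599 genes higher and 599 lower, against 269 and 264 for independent lists, with a correlation of log2 fold changes across genes of 0.429 and a covariance of 0.768. In YFP-positive macrophages they shared 750 higher and 563 lower, against 372 and 233, with a correlation of 0.368 and a covariance of 0.569. Simulated groups without a change, set against control libraries that were drawn as well, gave correlations of 0.499 and 0.492 and covariances of 0.132 and 0.130, as means of 20 simulations, with 0 genes shared as higher. Against the deposited controls, whose means the groups were drawn from, both were near 0 by design (0.0263 and 0.0373, 0.00357 and 0.00520). With the steady-state libraries split so that each comparison used a different pair, the means over 6 splits were correlations of 0.255 and 0.2798, covariances of 0.584 and 0.485, 388 and 271.5 genes shared as higher (209.8 and 99.9 for independent lists) and 356 and 286 shared as lower (203 and 88.7). Genes are not independent replicates. Spp1 and Trem2 were higher and Timd4 and Mgl2 lower in pancreatitis and in PDAC in both fractions.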

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

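Of the tests in this part, those on RNA from fibroblasts, the macrophage share, depth, a single library and biases in it, time of day, separate preparation and the splits that part the PDAC pairs were chosen after the result was seen. The other tests were not.

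The difference between the fractions changed with the tissue for collagen and ECM genes, among others, by the tests of interaction. From pancreatitis to PDAC, 67 genes and 15 lists (4 with an estimated correlation) changed differently in the fractions, with log2 differences of 4.25 for Serpinh1, 3.62 for Sparc, 3.19 for Bgn, 3.29 for Dcn, 4.06 for Col3a1, 3.94 for Col1a2 and 3.41 for Mgp, and, in the opposite direction, of -1.60 for Arpc3 and -0.84 for Arl8b. From steady state to PDAC, 227 genes and 21 lists (7 with an estimated correlation) did. The log2 differences were 3.10 for Bgn, 2.96 for Dcn, 2.47 for Sparc, 3.89 for Lum, 3.56 for Timp3 (an inhibitor of matrix proteases) and 2.89 for Serping1. They were 3.32 for Napsa, 2.16 for Ccr2, 1.21 for Vsig4, 1.48 for Timd4 and 2.33 for Gpnmb, and -2.39 for Prpf19 and -1.57 for Arpc3. Adgrg5 and Tnfrsf9, near 0 CPM in a group, had fitted differences of 5.90 and 4.65.

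From steady state to pancreatitis, 533 genes and 19 lists (0 with an estimated correlation in camera) changed differently. YFP-negative macrophages gained more in Gpr35 (log2 difference 2.89), Ccr2 (2.75), Fcrl1 (2.48), Fgr (2.41), Gdf3 (2.04), Napsa (1.87), C6 (1.58) and Vsig4 (1.12). They gained less or lost more in Junb (-4.73), Apoe (-4.31), Col3a1 (-2.50) and Sparc (-1.16). The levels of Apoe, a lipid carrier, were 33351, 120611, 12152 and 8895 CPM in pancreatitis YFP-positive replicates 1 to 4, and those of Junb were 243, 2081, 79.9 and 106 CPM. Replicate 2 is the library that stood apart, and without it the log2 differences were -2.67 for Junb and -3.09 for Apoe. Both calls ended without steady-state YFP-positive replicate 3 and without pancreatitis YFP-negative replicate 1, and that of Junb without each of 5 others.

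As many genes as in the real grouping were called in 1 of 100 drawn splits of the libraries for pancreatitis against steady state, the real split included, in 3 for PDAC against steady state and in 13 for PDAC against pancreatitis. The splits also break up the fractions' own difference, so they cannot exclude chance. The real and highest other counts were 533 and 524, 227 and 1231, and 67 and 261, in that order. With PDAC, 3 of 36 and 13 of 43 splits that part its 3 pairs called as many. Among these, all but the real one kept the PDAC fractions whole and regrouped the other libraries.

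Single libraries stood apart from the rest of their group of 4. Steady-state YFP-negative replicate 4 had a mean correlation of 0.922 with its group and a TMM factor of 1.16. Its sums were 25830.3 CPM for the lipid-associated and lysosomal list, 11591 for the scavenger and efferocytosis list and 983 for the B and plasma cell list. Steady-state YFP-positive replicate 3 had 3772 CPM for the interferon-stimulated list, and pancreatitis YFP-positive replicate 1 had 50.6 CPM for the endocrine islet cell list. Of 122 named genes, 5 were apart in steady-state YFP-negative replicate 4 and 11 in pancreatitis YFP-positive replicate 2, where chance gives 1.52 per library. By chance about 1 in 20 groups has such a library. Of 28 library measures 2 were apart, of 116 list sums 5, and of 488 pairs of a gene and a group 33.

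Collagen and ECM genes were higher in YFP-negative than in YFP-positive macrophages of PDAC. The T and NK cell list had a median log2 fold change of -1.46. Of the 11 lists of other cell types, 4 were higher and 2 lower. The T and NK cell list was also lower at steady state and in pancreatitis. Its fall may follow the sort for YFP, so it cannot decide on a lower macrophage share in general. A difference in depth was argued against, since 27 of 28 called collagen and ECM genes were still called after PDAC libraries were thinned. RNA from fibroblasts may contribute, because the 22 fibroblast list members on no ECM list had a median log2 fold change of 2.20, from -0.67 to 4.50, with 14 called higher, against 3.96 for the collagen list. Among them were Mfap5 (18.5 against 1.71 CPM), Cxcl12 (18.5 against 1.98), Pdgfra (8.70 against 0.380), Acta2 (21.7 against 4.41) and Gsn (403 against 643). The sort for CD45 would remove fibroblasts but did not keep out acinar RNA. Expression by YFP-negative macrophages themselves, the biological explanation, stays open too.

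More genes were lower than higher in YFP-negative macrophages in pancreatitis (15.3% of calls higher). A single library, pancreatitis YFP-positive replicate 2, was argued against as the whole cause of the imbalance, since 16.1% of the 683 calls were higher without it. The share was 27.8% without both outlying libraries, 28.2% with the block and 29.7% with voom. Of the 1093 genes called lower, 1085 stayed below 0 and 506 stayed called without it, and their median log2 fold change moved from -1.41 to -0.82. GC content bias and gene length bias in that library were argued against as the whole cause by the same 16.1%. The rank correlation of its deviation was 0.363 with GC content over 15697 genes and -0.124 with length, where the largest among 15 other libraries were 0.394 and 0.165 in size. A difference between the fractions stays open.

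Differences between PDAC and the other tissues covered 6519 to 6913 genes, clock genes included. A difference in depth was argued against, since the lowest ratio of calls after thinning to calls before was 0.975. Time of day of harvest stays open, since edgeR called 0 of 4 clock genes of the opposite phase higher than at steady state in both fractions while 5 of 6 in phase with Nr1d1 were lower in both. Of the 4, Cry1 and Npas2 were called in YFP-negative macrophages alone. PDAC libraries prepared apart from the others cannot be told apart from the tumour itself, since 0 of them had the digestion time of the other tissues. The tumour stays among the open explanations.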

How the results depend on the processing

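Leaving out the 2 outlying libraries and thinning the PDAC libraries were chosen after seeing the data, and the other alternatives were not. Of 5691 values for named genes under the alternatives, 5436 kept their direction and their side of the threshold, 233 lost the call, 21 gained it and 1 reversed, and 252 of 348 gene results kept both in all alternatives. Of 6090 values for gene lists, 5577 kept both, 324 lost the call, 171 gained it and 18 reversed, and 129 of 348 list results kept both in all. Of 180 values for overlaps of called genes, 148 stayed within 1.5 times and 32 moved.

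Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested. With the acinar share as a covariate, the counts were 150 for the fractions in PDAC, 212 and 604 for pancreatitis against steady state (YFP-negative and YFP-positive), 1377 and 358 for PDAC against steady state, 2245 for PDAC against pancreatitis in YFP-positive macrophages, and 131, 90 and 20 for the interactions. With only the groups compared in the fit, they were 533, 164 and 4121 for the fractions at steady state, in pancreatitis and in PDAC, 1530 and 1351 for pancreatitis against steady state and 16 for that interaction. DESeq2 gave 1870, 1968 and 1294 for the fractions and 1283, 441 and 280 for the interactions. Limma voom with library weights gave 5302 for the fractions in PDAC and 328, 862 and 636 for the interactions. Without a filter on low counts, the interaction of pancreatitis and steady state gave 891. Those of PDAC with steady state and pancreatitis gave 746 and 254 without the 2 outlying libraries.

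With each library left out in turn, the counts ran from 747 to 1981, 533 to 2119 and 306 to 570 for the fractions at steady state, in pancreatitis and in PDAC. They ran from 1590 to 3010 and 1872 to 3231 for pancreatitis against steady state, 5095 to 7344 and 5277 to 6207 for PDAC against steady state and 5502 to 6289 and 5093 to 6868 for PDAC against pancreatitis. For the interactions they ran from 44 to 1555, 99 to 288 and 25 to 77. Camera called 214 of 348 list results, from 206 to 218 with a library left out, and 62 with an estimated correlation, while fry called 206.

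The share of higher calls for the fractions was 31.4% at steady state, and 17.4% with only those groups. Leaving out 1 library gave 16.2 to 41.6% (YFP-negative replicates 4 and 2). The share was 15.3% in pancreatitis and 81.2% in PDAC, with alternatives given above. For the interaction of pancreatitis and steady state it was 24.8%, and 60.6% with the block, 41.2% with the acinar covariate, 87.5% with only those groups and 40.4% without the outlying libraries. For that of PDAC and steady state it was 95.2%, and 65.7% without the outlying libraries, 76.3% with only those groups and 56.4% with voom. For that of PDAC and pancreatitis it was 97%, and 75.2% without the outlying libraries and 61% with voom. DESeq2's size factors moved no share by over 10 points.

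With the replicate number as a block, the counts were 188 for the interaction of pancreatitis and steady state, 112 for that of PDAC and pancreatitis, and 1409, 1053 and 928 for the fractions at steady state, in pancreatitis and in PDAC. Where the numbers pair the libraries, the block changed no call that the report names but that of Cela2a, and it added the growth factor and dendritic cell lists for PDAC against pancreatitis in YFP-positive macrophages. At steady state and in pancreatitis every library correlated best with its own number in the other fraction, at 0.0764 to 0.129 and 0.0986 to 0.156, a hint from the data and not the design.

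Reversed directions follow, with the adjusted p and its range over the alternatives, and the cause was not tested. With the acinar share as a covariate, Cela2a had a log2 fold change of 0.17 for PDAC against steady state in YFP-negative macrophages. So adjusted, the interferon-stimulated list reversed for pancreatitis against steady state at 4.1e-07 (4.1e-07 to 0.682) and PDAC against steady state at 6.14e-06 (6.14e-06 to 0.954) (both YFP-negative), PDAC against pancreatitis (YFP-positive) at 0.000821 (0.000821 to 0.902) and its interaction at 0.000872 (2.18e-06 to 0.956). The immediate-early list reversed for the fractions in PDAC at 0.00616 (0.00616 to 0.818), pancreatitis against steady state at 0.0898 (0.000815 to 0.483) and 0.00131 (0.00131 to 0.915), and the interaction of PDAC and pancreatitis at 0.186 (0.00257 to 0.642), as did the inflammatory list there at 0.0258 (0.0258 to 0.997). The acinar list, which the covariate was made from, reversed for the fractions in PDAC at 0.641 (1.93e-44 to 0.641) and the interaction of PDAC and steady state at 0.491 (1.37e-27 to 0.491). The tissue-resident and dendritic cell lists reversed for pancreatitis against steady state in YFP-negative macrophages at 0.794 (0.00907 to 0.794) and 0.968 (0.000973 to 0.968). The erythroid list reversed for PDAC against steady state in them at 0.694 (0.000254 to 0.694) and the ductal list for PDAC against pancreatitis in YFP-positive ones at 0.0353 (0.0353 to 0.952). Without PDAC YFP-positive replicate 1 the interferon-stimulated list reversed for the interaction of PDAC and pancreatitis at 0.956 (2.18e-06 to 0.956), and without PDAC YFP-negative replicate 1 for the fractions in PDAC at 0.0332 (1.21e-09 to 0.977), where leaving out 1 library gave 0.00438 to 0.658. Without the 2 outlying libraries the cell cycle list reversed for the interaction of pancreatitis and steady state at 0.00319 (0.00319 to 0.96).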

Other observations

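In this part the clock genes were chosen after values of Nr1d1 and Arntl, among others, were seen. The count of splits that part pairs was chosen after the result was seen, and the other splits were not.

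Mgl2 fell in pancreatitis and was higher in PDAC, below its steady-state levels of 1452 and 1771 CPM. Mgl2 was at 806 ± 305 against 87.8 ± 14.1 CPM in PDAC and pancreatitis in YFP-negative macrophages (log2 fold change 3.20, SE 0.27, adjusted p = 1.74e-08) and at 967 ± 275 against 105 ± 21.0 CPM in YFP-positive ones (log2 fold change 3.20, SE 0.27, adjusted p = 1.93e-08). The alternative activation list was higher in PDAC than in pancreatitis in YFP-negative macrophages (camera adjusted p = 0.000548, adjusted p = 0.0687 with an estimated correlation) and in YFP-positive ones (camera adjusted p = 0.000584, adjusted p = 0.0917 with an estimated correlation). In each fraction, 13 of its 24 genes were higher, 7 lower and 4 not called (13 higher and 7 lower over the list alone). Vegfa, the growth factor of blood vessels, was at 85.4 ± 28.5 against 0.659 ± 0.209 CPM (log2 fold change 7.01, SE 0.55, adjusted p = 6.11e-09) and at 59.0 ± 5.87 against 1.03 ± 0.537 CPM (log2 fold change 5.78, SE 0.52, adjusted p = 3.36e-08), with 1.08 and 1.04 CPM at steady state.

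Output genes of the circadian clock were low in PDAC in both fractions. Nr1d1 was at 4.44 and 3.75 CPM in YFP-negative and YFP-positive macrophages of PDAC, against 148 and 163 CPM at steady state and 230.5 and 168 CPM in pancreatitis. Log2 fold changes from steady state to PDAC in YFP-negative and YFP-positive macrophages were -2.58 and -2.67 for Nr1d2, -3.38 and -3.33 for Dbp, -3.20 and -2.91 for Tef and -2.70 and -2.76 for Per3, all called by edgeR. Those of Arntl, whose protein drives these genes, were -0.17 and -0.88 (adjusted p = 0.82 and 0.19). Those of Clock were 0.09 and -0.03 (adjusted p = 0.756 and 0.92) and those of Ciart, in phase with Nr1d1, -1.10 and -1.15 (adjusted p = 0.297 and 0.275). Cry1 was called in YFP-negative macrophages alone (1.81 and 1.55, adjusted p = 0.0457 and 0.083), as was Npas2, at 0.642 against 0 CPM (adjusted p = 0.00291) and 0.325 against 0.218 CPM (adjusted p = 0.693).

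Of 35 splits of the libraries, only the real one called as many genes, for each comparison of groups but the fractions in PDAC. Unadjusted over comparisons, this count cannot exclude chance. For PDAC against pancreatitis in YFP-positive macrophages 8 splits part the 3 pairs, too few for a share under 0.05 (2952 in the highest other). If replicate numbers pair the fractions outside PDAC, too few splits part those pairs too. The real and highest other values for the fractions were 1147 and 10 at steady state and 1290 and 280 in pancreatitis. In YFP-negative macrophages they were 2542 and 2 (pancreatitis against steady state), 6633 and 5380 (PDAC against it) and 6913 and 3133 (PDAC against pancreatitis). In YFP-positive ones they were 2816 and 664, 6755 and 3099, and 6519 and 4573. The fractions in PDAC allow 10 splits, too few for a share under 0.05 (714 genes called in the real split, 3 in the highest other). The 3 other splits that part all 3 pairs of replicate numbers called 0 genes by edgeR, and the 6 that part 1 pair called at most 3.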
